A study of Mus musculus with 8 samples.

How the data were processed

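Gene expression was measured with a mouse gene expression array in club cells, the secretory cells of the airway lining, isolated from lungs of Atgl KO/cTg and wt/cTg mice. Atgl is the older name of Pnpla2, which encodes adipose triglyceride lipase, the enzyme that starts the breakdown of stored triglycerides. The labels do not expand cTg, and both genotypes carry it. Each array held RNA pooled from 3 or 4 mice, in all 16 mice without Atgl and 14 with it, so each replicate is a pool and the spread between replicates is a spread between pools. The groups were taken from the genotype label, 4 arrays per genotype. The replicate numbers used here follow the order of the samples and pair nothing.

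Per the labels' protocols, RNA was extracted with a miRNeasy Micro kit with DNase treatment on the column, and 50 ng was amplified with the NuGEN Ovation Pico WTA system and labelled with biotin. The deposited values are log2 signals, 1 per probe set and array, and were used as deposited. The log2 unit was read from the values, which ran from 1.85 to 13.5 with array medians of 5.12 to 5.24. The software, background correction and normalization method are not given in the sources used here. No scanner files, detection p-values, slides or scan dates were used here, so signal above background could not be tested and no batch could be set against genotype. The number of arrays limits the precision.

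The table held 41345 probe sets. In the platform annotation 23521 had 1 gene symbol, 1814 had several and 16010 had none, and names were taken only from probe sets with 1 symbol. Of a gene's probe sets, the one with the highest mean over the 8 arrays was kept, which gave 22180 genes. Genes with a mean at or below the median of all probe sets (5.18) were left out, and 13112 genes were tested. No pair of arrays held identical values, and correlations between arrays ran from 0.965 to 0.985.

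Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are Atgl KO/cTg minus wt/cTg on the log2 scale. For single genes and list scores an exact two-sided permutation test over the 70 arrangements of 8 arrays was added, whose smallest possible p is 0.0286. Gene lists of pathways and cell types, 43 in all, were fixed before the data were examined, and 40 had the 5 tested members needed. They were tested with camera at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. A list score is the mean log2 value of its tested members on an array. Figures were drawn with matplotlib 3.10.9.

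The genes named were set by a rule fixed before the data were examined. It took Pnpla2, up to 12 genes per direction with the largest change among those past the threshold with non-overlapping groups, and genes that filled a direction up to 6 by smallest p. It also took up to 4 members of each list that passed camera (2 where no member passed), up to 2 of every other list, and a set of lipase, club cell and other marker genes. Members of the sex-linked list are also named, and a gene named outside the rule is given as named after its values were seen.

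The steps were tested on simulated data, with 200 of 13112 genes changed in 10 runs of this comparison. The fit recovered 44.2% of genes changed by 0.5 on the log2 scale, 90.4% at 1 and 97.9% at 1.5, with 4.74% false among those called. These shares hold for 200 changed genes, and the adjustment is stricter where fewer genes change. In the real data 13 genes passed, so the shares can be too high for it. There Lamp3 (-1.53, limma adjusted p = 0.0294) passed and Cxcl5 (1.28, 0.179) did not. In the same runs camera found a list shifted by -0.5 in 10 of 10 runs and called 11 other lists in total. Splits of the real arrays that did not follow genotype gave up to 20 lists. The simulated runs therefore do not show how often camera calls lists wrongly in these data.

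Alternatives covered the level filter, the variance prior, quantile normalization, median centring, array weights, the mean of a gene's probe sets, age, sex-linked transcripts, runs of mouse numbers, each array left out, thresholds and set tests. After the data were examined, further alternatives were added: both arrays at the ends of the first principal component left out, list scores by exact permutation, lists without shared genes, and camera without a variance trend. The last of these was the form run first, when the values were explored. The form with the trend is reported as the main one, to match the variance trend of the gene test.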

Results

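Club cells of Atgl KO/cTg mice were compared with club cells of wt/cTg mice, all carrying cTg and aged 38 to 48 weeks. There were 4 arrays per genotype, each from a pool of 3 or 4 mice. The series' design text speaks of 4 sets, each Atgl KO/cTg versus wt/cTg, but the labels do not say which samples form a set. The question the design poses is which transcripts differ in club cells between Atgl KO/cTg and wt/cTg mice.

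Pnpla2, the gene that was knocked out (probe set 17484909), was lower in every Atgl KO/cTg pool than in any wt/cTg pool. Its log2 signal was 6.98 ± 0.20 (SD, n = 4) in Atgl KO/cTg and 8.70 ± 0.11 (SD, n = 4) in wt/cTg. The log2 difference was -1.72 (SE 0.11, limma adjusted p = 0.000116, exact permutation p = 0.0286, the smallest possible), a level of 0.304 of the control. The Atgl KO/cTg arrays read 6.99, 7.16, 7.09 and 6.70, and the wt/cTg arrays 8.70, 8.63, 8.62 and 8.86. Whether the probes lie in the deleted part of the gene is not given in the sources used here.

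Besides Pnpla2, 12 genes passed the limma threshold, most of them lower in Atgl KO/cTg. Of all 13 genes, 11 fell and 2 rose, and all 13 had groups that did not overlap. The other lower genes were Lamp3, Hc, Egfl6, Itih4, Mme, Slc34a2, Etv5, Actc1, Tnnt2 and Sftpc, and the higher genes were Wfdc21 and Ptgs2. At an unadjusted p under 0.05 there were 1043 genes, 445 higher and 598 lower. Groups did not overlap for 571 genes, 4.36% of those tested against 2.86% by chance.

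The count of 13 rested on single arrays and on settings, while Pnpla2 passed in all 20 refits. Without 1 array limma called 1 gene (without Atgl KO/cTg replicate 1, wt/cTg replicate 2 or wt/cTg replicate 4), 2 genes (without Atgl KO/cTg replicate 3, Atgl KO/cTg replicate 4 or wt/cTg replicate 3), 18 genes (without Atgl KO/cTg replicate 2) or 25 genes (without wt/cTg replicate 1), and after quantile normalization or without the variance trend it called 1. It called 7 without a level filter or with age as a covariate, 8 without both arrays at the ends of the first principal component, and 23 with array weights. Median centring called 1 gene higher and 18 lower.

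**Figure D1:**
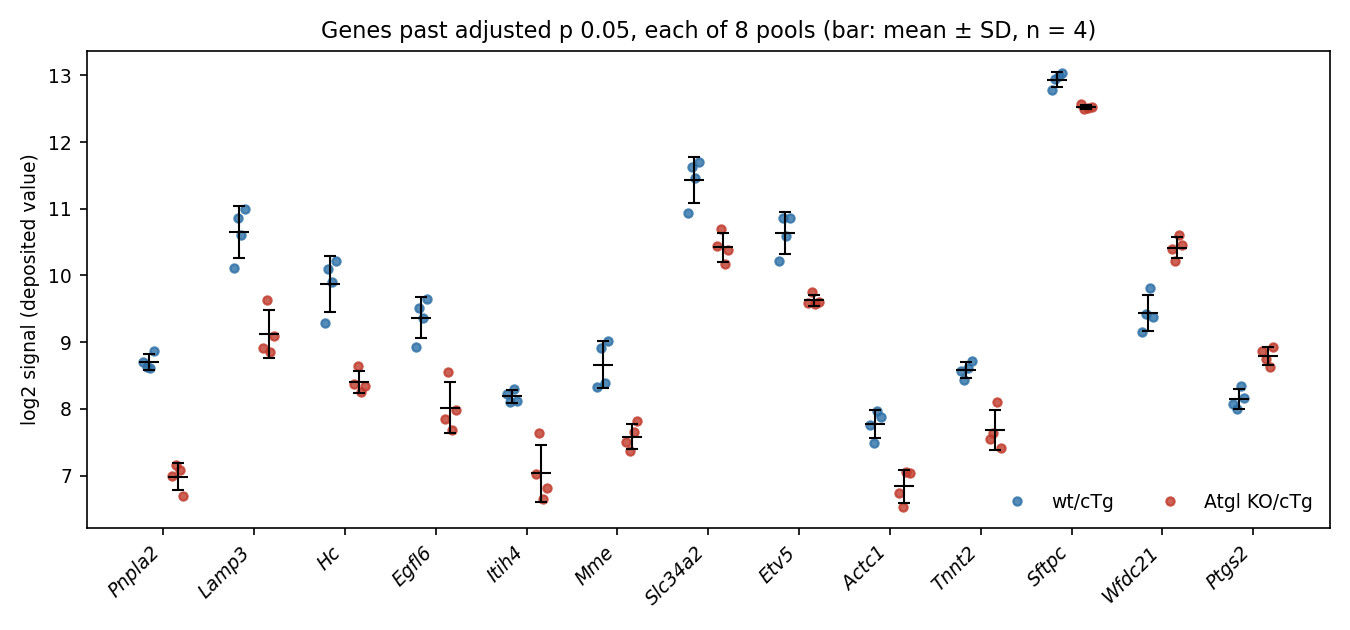
Log2 signal (deposited values, vertical axis) of the 13 genes past the limma threshold in each of the 8 pools, wt/cTg in blue and Atgl KO/cTg in red, with mean ± SD (n = 4). The genotypes do not overlap for any of the 13 genes; the Pnpla2 difference is -1.72.

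Transcripts of alveolar type 2 cells, which make surfactant, were lower in Atgl KO/cTg. All 15 tested members of this list lay below 0, with a median log2 difference of -0.65. Over all genes 5 members fell, and adjusted over the list alone all 15 fell. Lamp3, a protein of the lamellar bodies that store surfactant, fell by 1.53 (SE 0.20, limma adjusted p = 0.0294), and Hc, complement component C5, fell by 1.47 (SE 0.18, limma adjusted p = 0.0286). Etv5, a transcription factor of alveolar type 2 cells, fell by 1.01 (SE 0.13), Slc34a2, a phosphate transporter, by 1.01 (SE 0.16), and Sftpc, surfactant protein C, by 0.41 (SE 0.06), with limma adjusted p of 0.0294, 0.0477 and 0.0461. Of the 15 members, 9 are also on another fixed list. Camera gave an adjusted p of 1.43e-27 at the preset correlation and adjusted p = 0.209 with an estimated correlation. The list score fell from wt/cTg to Atgl KO/cTg in an exact permutation test (p = 0.0286, the smallest possible) and in fry (adjusted p = 0.0408).

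The surfactant list overlaps with that list and had 15 of 17 members below 0 (median -0.16). Over all genes 3 members fell. Adjusted over the list alone 7 fell and 1 rose. Lpcat1, an enzyme of surfactant phospholipid synthesis, had a log2 difference of -0.90 (limma adjusted p = 0.0617 over all genes). Camera's adjusted p was 4.98e-07 and adjusted p = 0.56 with an estimated correlation. The exact permutation p of its score was 0.0286. Without the genes it shares with other passing lists, an alternative chosen after the data were seen, the median was -0.02 and camera no longer passed the list (adjusted p = 0.467).

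Part of the cardiac muscle and adipocyte list was also lower, with 7 of 10 tested members below 0 and 3 above. Actc1 and Tnnt2, parts of the contractile apparatus of heart muscle, fell by 0.93 (SE 0.14) and 0.90 (SE 0.14), both with a limma adjusted p of 0.0477. Adjusted over the list alone 5 members fell, among them Myl7 (-0.64) and Myl4 (-0.51). The list median was -0.31 (-0.09 without the level filter), camera's adjusted p was 3.07e-05 and adjusted p = 0.209 with an estimated correlation, the fry adjusted p was 0.0408 and the exact permutation p 0.0286. Outside the cell type lists, Egfl6 fell by 1.35 (SE 0.19), Itih4 by 1.15 (SE 0.18) and Mme, a membrane metallopeptidase, by 1.08 (SE 0.16), with limma adjusted p of 0.0461, 0.0477 and 0.0477.

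Transcripts of fibroblasts and smooth muscle, endothelium and alveolar type 1 cells lay mostly below 0. In the fibroblast and smooth muscle list 18 of 20 members lay below 0 (median -0.36). None passed over all genes, and adjusted over the list alone 4 fell: Tcf21, a mesenchymal transcription factor (8.06 against 9.06 in wt/cTg), Cnn1 (-0.81), Actg2 (-0.65) and Gsn (-0.35). That count was 8, 7 and 10 without Atgl KO/cTg replicate 3, Atgl KO/cTg replicate 4 and wt/cTg replicate 2, and 0 without both arrays at the ends of the first principal component. The endothelial list had 16 of 19 members below 0 (median -0.28), with Calcrl at -0.48 and Car4 at 0.37. The alveolar type 1 list had 14 of 15 members below 0 (median -0.21), with Limch1 at -0.68 and Emp2 at -0.33. Emp2 ran from -0.38 to -0.19 when each array was left out. In the extracellular matrix list 17 of 23 members lay below 0 (median -0.24), while Mmp12, a macrophage metalloproteinase, rose by 0.84 adjusted over the list alone. No member of the endothelial or type 1 list passed. Camera passed the 4 lists, with adjusted p = 0.56 (fibroblast) and adjusted p = 0.621 (the other 3) with an estimated correlation, and exact permutation p of 0.0857, 0.314, 0.229 and 0.171. With both arrays at the ends of the first principal component left out, the endothelial median was -0.05 and the type 1 median 0.00247, and camera's direction turned for both lists. Without wt/cTg replicate 4 alone the medians were -0.12 and -0.04 and neither list passed (adjusted p = 0.255 and 0.26), nor did they without Atgl KO/cTg replicate 2 (-0.22 and -0.15, adjusted p = 0.118 and 0.0535). The matrix list did not pass without wt/cTg replicate 1 (-0.16, adjusted p = 0.0961). Leaving out both end arrays was chosen after the data were seen.

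**Figure D2:**
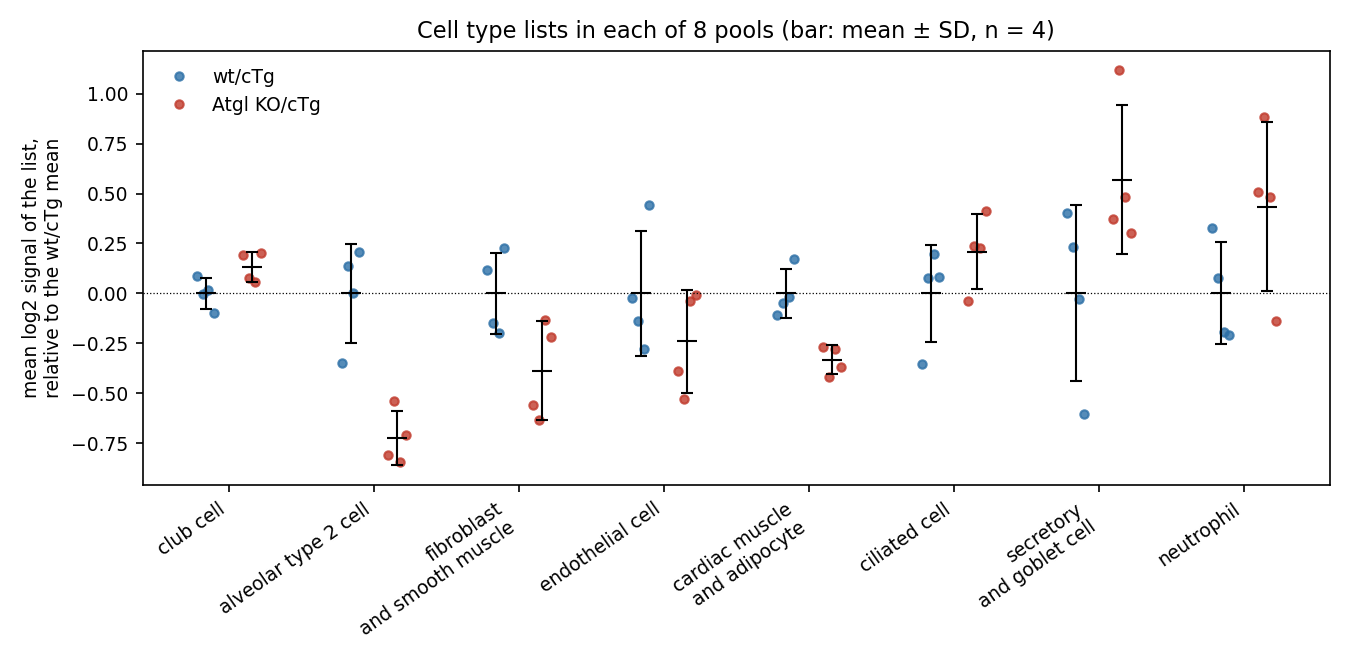
Mean log2 signal of 8 cell type lists in each pool, relative to the wt/cTg mean of the list (vertical axis, log2), wt/cTg in blue and Atgl KO/cTg in red, with mean ± SD (n = 4). The alveolar type 2 and cardiac lists do not overlap between genotypes, and the other lists plotted do.

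Wfdc21, a small secreted protein, and Ptgs2, the inducible cyclooxygenase, were higher in Atgl KO/cTg. Wfdc21 rose by 0.98 (SE 0.13, limma adjusted p = 0.0294) and Ptgs2 by 0.65 (SE 0.10, limma adjusted p = 0.0477). The next genes by p value did not pass over all genes: Slc23a1 (0.52, limma adjusted p = 0.114), Clec4n (0.72, 0.124), Cxcl5, a neutrophil-attracting chemokine (1.28, 0.179), and Colca2 (0.60, 0.231).

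Goblet cell, ciliated cell and neutrophil transcripts lay above 0 in Atgl KO/cTg, but no member of these lists passed over all genes or adjusted over the list alone. In the goblet list 17 of 17 members lay above 0 (median 0.34), with the gel-forming mucin Muc5ac at 1.04 and the membrane mucin Muc4 at 0.78. When each array was left out, Muc5ac ran from 0.67 to 1.24 and Muc4 from 0.48 to 0.92. In the ciliated list 23 of 24 lay above 0 (median 0.19), with Spag6l at 0.55 and Foxj1 at 0.35. In the neutrophil list 12 of 12 lay above 0 (median 0.46), with Mmp8 at 0.87 and S100a9 at 0.56. Camera passed these lists, with adjusted p = 0.56, adjusted p = 0.621 and adjusted p = 0.56 with an estimated correlation, and the exact permutation p were 0.0857, 0.229 and 0.143. Single pools moved these medians: without Atgl KO/cTg replicate 2 the goblet median was 0.20 and the neutrophil median 0.25, and the goblet median was 0.55 without wt/cTg replicate 1 and 0.53 without wt/cTg replicate 2. The ciliated median was 0.06 without wt/cTg replicate 1, where camera did not pass the list (adjusted p = 0.0961), and 0.29 without wt/cTg replicate 3.

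Club cell markers differed little. Scgb1a1 (-0.07, limma adjusted p = 0.828), Scgb3a2 (-0.09, 0.847) and Cyp2f2 (0.06, 0.798) did not pass, and Scgb1a1 read 12.92 ± 0.10 in Atgl KO/cTg and 12.99 ± 0.08 in wt/cTg (SD, n = 4). The highest values of the arrays were 13.38 to 13.54, so these levels do not show an unchanged share of club cells. Transcripts of other cell types read about as high, such as Sftpc (12.53 and 12.94) and Ighm (12.86 and 12.41). Differences can therefore not be assigned to club cells alone. The list had 22 of 28 members above 0 (median 0.12). Adjusted over the list alone Retnla (0.36), Gabrp (0.34) and Cckar (0.41) rose, and none did over all genes. Camera's adjusted p was 1.22e-05 and adjusted p = 0.56 with an estimated correlation, and the median was 0.08 without Atgl KO/cTg replicate 1. In the inflammatory list 18 of 26 members lay above 0 (median 0.12). Ptgs2 rose over all genes, and adjusted over the list alone Ptgs2 and Cxcl5 rose while Cxcl15, a lung epithelial chemokine, fell by 0.31. Cxcl15 is also on the alveolar type 2 list. The inflammatory list's camera adjusted p was 0.0062, and adjusted p = 0.621 with an estimated correlation. The inflammatory list did not pass without wt/cTg replicate 4 (median 0.00, adjusted p = 0.118), Atgl KO/cTg replicate 2 (0.05, 0.0999) or Atgl KO/cTg replicate 1 (0.15, 0.0948), and its median was 0.27 without Atgl KO/cTg replicate 4. The antioxidant list had 15 of 23 members above 0 (median 0.11), with Nqo1 at 0.58 and Slc7a11 at 0.81, and adjusted p = 0.606 with an estimated correlation. It did not pass camera without wt/cTg replicate 2 (median 0.03, adjusted p = 0.231) or Atgl KO/cTg replicate 1, 3 or 4 (adjusted p = 0.108, 0.187 and 0.0714), and its median was 0.05 without Atgl KO/cTg replicate 2.

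Genes of lipid storage and breakdown did not move as a group. In the lipolysis and lipid droplet list 18 members lay above 0 and 14 below. Its median (0.04) and its mean (-0.07) differ in sign, and Pnpla2 itself was the only member to fall over all genes. Adjusted over the list alone Pnpla2, Lpcat1 and Ddhd2 (named after its values were seen) fell. Abhd5, the activator of the lipase (0.06), G0s2, its inhibitor (-0.37), Lipe, hormone-sensitive lipase (0.01), and Plin2, a lipid droplet coat protein (0.01), did not pass, and the signs of Abhd5, Lipe and Plin2 turned in other settings. G0s2 ran from -0.57 to -0.29 when each array was left out. Camera's adjusted p was 0.879. Fry's test of change in either direction gave 1.63e-06 with Pnpla2 among the members.

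Fatty acid oxidation genes, a target group of the receptor PPAR alpha, gave a median of -0.04 with 18 of 28 members below 0, none passing over all genes or over the list alone. Fry's test of change in either direction gave an adjusted p of 0.0119. Cpt1a, which brings fatty acids into mitochondria, was at -0.34 (limma adjusted p = 0.379) and Angptl4 at -0.77 (0.439). Ppara lay below the level filter, at 5.08 ± 0.22 and 5.19 ± 0.13 (SD, n = 4, exact permutation p = 0.4). Electron transport chain genes had a median of -0.01 over 72 members. In the fatty acid synthesis list 16 of 24 members lay below 0 (median -0.09). Adjusted over the list alone Fasn (-0.65), Scd1 (-0.51) and Elovl1 (-0.46) fell, and Fasn is also on the alveolar type 2 list. Its camera adjusted p was 0.00395, with 0.00946 in fry's test of either direction, and adjusted p = 0.606 with an estimated correlation. The median was -0.05, -0.14 and -0.15 without Atgl KO/cTg replicate 1, 2 and 4, and -0.04 without wt/cTg replicate 2.

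**Figure D3:**
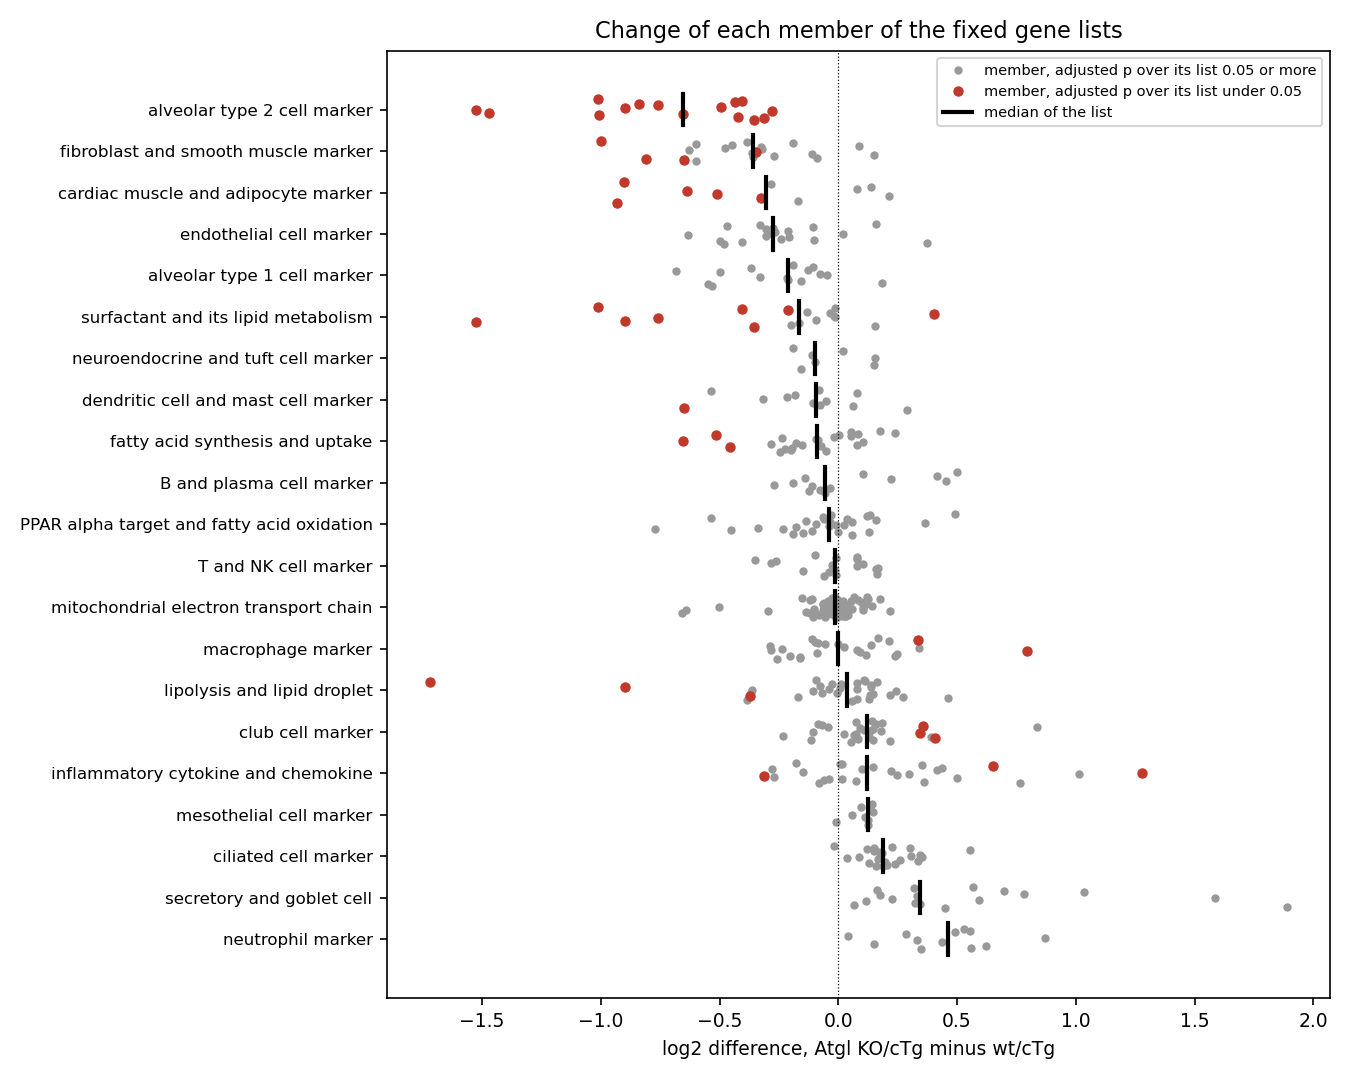
Log2 difference of each tested member (horizontal axis, Atgl KO/cTg minus wt/cTg) in cell type and lipid lists, 1 list per line, with members past an adjusted p over their list alone in red and the list median as a black bar. All 15 alveolar type 2 members lie below 0 and pass over the list, while the 17 goblet members lie above 0 and none passes.

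Across the lists, camera passed 17 of 40 at the preset correlation, 6 higher and 11 lower. With an estimated correlation camera passed 0, and 3 lists had an unadjusted p under 0.05. Fry's directional test passed 2 lists, the alveolar type 2 and cardiac lists, and the exact permutation test gave p under 0.05 for 3, those and the surfactant list. Fry's test of either direction passed 8. Among the 8 were the lipolysis list, which holds the knocked-out Pnpla2, and the liver X receptor list (adjusted p = 0.0138), which camera did not pass. In the latter, 1 member rose (Ch25h, 0.65) and 2 fell, among them Abca3 (-0.36), adjusted over the list alone. Abca3 is also on the alveolar type 2 and surfactant lists. The remaining lists passing camera were MHC class II (median -0.16, H2-Ab1 -0.22), dendritic and mast cells (-0.09, Cd209a -0.65) and the cytosolic ribosome (-0.05, Rpl23a -0.19 and Rps16 0.53), with adjusted p = 0.621, adjusted p = 0.606 and adjusted p = 0.704 with an estimated correlation. Each of these 3 lost its camera call without wt/cTg replicate 3 (adjusted p = 0.376, 0.133 and 0.426, with medians of -0.07, -0.09 and -0.02). The MHC list also lost it without Atgl KO/cTg replicate 4 (0.17), the dendritic list without Atgl KO/cTg replicate 1 or 4 (0.0596 and 0.391), and the ribosome list without Atgl KO/cTg replicate 2 or 3 or wt/cTg replicate 4 (0.199, 0.0987 and 0.132). The dendritic median was -0.14 and -0.19 without Atgl KO/cTg replicate 2 and 3, and the ribosome median -0.03 without Atgl KO/cTg replicate 2. The other 23 lists did not pass (camera adjusted p 0.0749 to 0.957), among them macrophage, T and NK cell, B cell, cell cycle, interferon, unfolded protein response and cholesterol synthesis genes. In the macrophage list 12 members lay above 0 and 13 below. Adjusted over that list alone Ctsk (0.79) and Plet1 (0.34) rose, and neither passed over all genes (limma adjusted p = 0.293 and 0.278). Ptprc, a marker of all leukocytes, read 10.41 and 10.52.

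Sex-linked transcripts differed between pools. Xist, transcribed from the inactive X chromosome, read 3.75 in wt/cTg replicate 4 and 9.34 to 10.67 in the other pools, and that pool had the highest Y-linked Uty (5.92), Kdm5d (7.05) and Eif2s3y (7.996). Among the other pools, Kdm5d was higher in Atgl KO/cTg (5.745 to 6.507) than in wt/cTg (5.273 to 5.506). So was Eif2s3y (6.486 to 7.17 against 6.03 to 6.364), while Uty overlapped (4.518 to 5.506 against 4.184 to 4.846). With a score of these transcripts (Xist minus the mean of the Y-linked ones) as a covariate, the alveolar type 2 median was -0.64 and the fibroblast median -0.34. The alveolar type 1 median was -0.14 (-0.21 in the main fit) and the endothelial median -0.21 (-0.28 in the main fit).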

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

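Of the tests in this part, the comparisons of ciliated with fibroblast and with alveolar type 2 scores, those of the macrophage score, the exact permutation of the fixed lists' scores, the reading of Xist and the count of splits without Pnpla2 were chosen after the result was seen, and the others were set before.

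Lower alveolar type 2 transcripts were the clearest pattern after Pnpla2 by members passing, with all 15 past the threshold over the list alone. The exact permutation p was 0.0286, but camera gave adjusted p = 0.209 with an estimated correlation, and the cardiac list had the same 2 values. The median stayed at -0.588 or lower whichever array was left out, so 1 array does not account for it. It was -0.64 with the sex score as a covariate, which argues against the sex of the pools. That fit leans on wt/cTg replicate 4, with a score of -3.24. In the other pools the score ran with genotype, at 3.15 to 4.81 in Atgl KO/cTg and 5.11 to 5.23 in wt/cTg. Sex composition is therefore not excluded. A higher share of club cells would lower other cell types alike. The ciliated minus alveolar type 2 score was higher by 0.93 in Atgl KO/cTg (exact permutation p = 0.0286), and by 0.872 or more whichever array was left out. It was chosen with both changes known, -0.725 for alveolar type 2 and 0.209 for ciliated cells (exact permutation p = 0.229). Its p-value thus adds little to the alveolar type 2 fall. The ciliated score did not fall, which argues only against a fall of all other cell types alike. Ciliated cells line the airway as club cells do, so this comparison cannot test a preparation richer in airway cells as a whole. A second list of 12 alveolar type 2 genes had 9 members below 0 and a median of -0.12 (exact permutation p = 0.143). Fewer alveolar type 2 cells in the preparation, or a lower activity of the whole programme, can therefore not be told apart from a change in part of its genes. No test here separates these explanations.

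Fibroblast transcripts lay mostly below 0 (18 of 20 members), with an exact permutation p of 0.0857 for the score and adjusted p = 0.56 with an estimated correlation. The median was -0.34 with the sex score as a covariate. That argues against sex composition only weakly, since this fit too leans on wt/cTg replicate 4. A second fibroblast list had 12 of 12 members below 0 with a median of -0.25 (exact permutation p = 0.0857), as fewer mesenchymal cells in the Atgl KO/cTg preparations could give. Gsn, which other cells also express, read 10.75 against 11.09, and 4 of the 20 members of the first list are on another list. The ciliated and macrophage scores minus the fibroblast score were higher by 0.60 and 0.42 (both exact permutation p = 0.0571), which missed the threshold. The macrophage score itself changed by 0.0298 (95% confidence interval -0.11 to 0.17), and 0 of its 25 members lay as low as the fibroblast median of -0.36. Its mean includes 2 members that rose over the list alone, Ctsk (0.79) and Plet1 (0.34). These values argue against dilution of all other cell types alike as the whole cause of a change of that size.

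The 13 genes and 17 lists differ in how often other splits of the arrays gave as many. Only 1 of the 35 splits of the 8 arrays, the real one, gave 13 genes, or 12 without Pnpla2, which differs by design, and the highest other split gave 1. That share of 0.0286 is the smallest possible with 8 arrays and belongs to the main setting. The count was 1 after quantile normalization or without the variance trend, and 1 to 25 when single arrays were left out. Chance is therefore unlikely to give the count at the main setting, but it is not excluded for the 12 genes besides Pnpla2. For the lists 7 of the 35 splits gave as many as 17, and the highest other gave 20, so chance cannot be excluded for the list count at the preset correlation.

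The arrays of 1 pool or another lay far from the other 3 of their genotype in 21 of 298 groups of 4 values, against 14.9 that chance gives at 1 in 20. In wt/cTg replicate 4, Xist read 3.749, Kdm5d 7.0529 and Eif2s3y 7.9965, values that a pool without female mice would show, and sex is not in the labels used here. The same pool stood apart for Retnla (11.16), Emp2 (10.876) and Trp53inp1 (7.6312).

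In wt/cTg replicate 1, Scgb1a1 read 12.877, Gabrp 11.206 and the unfolded protein response list 9.1976, and in wt/cTg replicate 2 Angptl4 read 5.7599. In Atgl KO/cTg replicate 1, Fosb read 7.764 and the lipolysis list 7.2761. In Atgl KO/cTg replicate 2, Muc4 read 8.829, Rpl23a 11.53, the interferon list 7.9065 and the first principal component -28.605, with the other 3 pools of that genotype between -2.97 and -0.03. In Atgl KO/cTg replicate 3, G0s2 read 8.7444, Cckar 10.454 and Muc16 9.4854. In Atgl KO/cTg replicate 4, Abhd5 read 8.8876 and H2-Ab1 11.682.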

How the results depend on the processing

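The alternatives chosen after the data were seen were leaving out both arrays at the ends of the first principal component, exact permutation of list scores, lists without shared genes, camera without a variance trend, and the counts over the list alone per setting. Pnpla2 kept its direction and passed in all 20 refits, with log2 differences from -1.78 to -1.62. The count of 13 genes was 7 without a level filter, 1 without the variance trend, 1 after quantile normalization, 23 with array weights, 7 with age as a covariate, 3 with runs of mouse numbers as a block, 8 without both arrays at the ends of the first component, 20 at an adjusted p under 0.1, and 1 to 25 when each array was left out; the cause was not tested. Of the other 12 genes, Wfdc21 passed in 12 refits, Lamp3 and Hc in 11, and Ptgs2 in 4. The count of 17 lists was 0 with an estimated correlation, 2 with fry and 3 by exact permutation, and 14 to 19 in the other alternatives. Over the list alone, 13 to 15 alveolar type 2 members fell across the refits (15 in the main setting), 5 to 9 surfactant members (7), 3 to 6 cardiac members (5) and 0 to 10 fibroblast members (4).

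The labels give no shared replicate numbers, so the block of mouse-number runs was only a guess at shared sets. Of the 4 pairs of pools of different genotype within a run, the deviations correlated at -0.08, 0.14, -0.06 and 0.11, so not every pair was above 0.1, and the block was not taken as a pairing.

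Settings other than single arrays also ended camera calls. Without both end arrays the inflammatory (median -0.02), matrix and ribosome lists did not pass, with the block of mouse numbers the MHC class II, dendritic and ribosome lists, with array weights the endothelial, matrix and dendritic lists, and without a level filter the inflammatory and antioxidant lists. The antioxidant list was also lost with the stricter filter, median centring and age, the matrix list with the stricter filter, and the ribosome list with quantile normalization and the sex score. Without both end arrays the goblet median was 0.15, the neutrophil median 0.27 and the fibroblast median -0.22, and the block gave a ciliated median of 0.35.

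Signs turned for genes near 0. Lipe was -0.0209 with median centring, -0.00135 with array weights, -0.0243 with the block of mouse numbers and -1.76e-05 with the sex score, and -0.0445 to 0.0852 when each array was left out. Plin2 was -0.0168 with median centring, -0.00505 with age and -0.0932 to 0.0737 when each array was left out. Abhd5 ran from -0.00345 to 0.117 and Scgb3a2 from -0.126 to 0.00697 when each array was left out. Without both arrays at the ends of the first component Scgb3a2 was 0.0245, Oas2 -0.0808, the median of the alveolar type 1 list 0.00247 and that of the endothelial list -0.0474 with camera's direction turned. Of 1976 named-gene values 1807 kept their direction and side of the threshold, 141 no longer passed, 13 newly passed and 15 turned. Without detection p-values, signal over background could not be set against any of these.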

Other observations

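The tests of list scores against the first principal component were chosen after the result was seen, and the test of the neighbours of Pnpla2 was set before.

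List scores were set against the main axis of variation between pools, and none passed after adjustment. The first principal component held 29.3% of the variance, and the goblet score ran from 7.25 in wt/cTg replicate 4 to 8.97 in Atgl KO/cTg replicate 2, the pools at its ends. Over the 8 pools the correlation with the goblet score was r = -0.96 (exact permutation p = 0.00169, adjusted p = 0.0676 over 41 list scores) and rho = -0.79 (exact permutation p = 0.0279, adjusted p = 0.286). Without the 2 pools farthest from the median r was -0.79. The cardiac score gave r = 0.85 (exact permutation p = 0.0033, adjusted p = 0.0676), rho = 0.90 (exact permutation p = 0.00456, adjusted p = 0.187) and r = 0.85 without those 2 pools. The component was computed from genes that include those of the lists.

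Genes next to Pnpla2 were looked at because strain variants carried along with a knocked-out gene could change its neighbours. In the gene order of the RefSeq table of GRCm38.p6, 5 of the 40 nearest tested genes had an unadjusted p under 0.05 (12.5%, against 7.93% of all other genes, one-sided Fisher's exact p = 0.209), which does not decide. The 5 were Muc5ac and, named after their values were seen, Muc5b, Rassf7, Rplp2 and Cracr2b, all above 0, and Muc5ac and Muc5b are also goblet genes. Rplp2 (0.32) and Cracr2b (0.33) are the nearest tested genes on either side of Pnpla2. Neither passed over all genes (limma adjusted p = 0.557 and 0.51). The next tested genes outward, Pidd1 and Cd151, also named after their values were seen, were at 0.003 and -0.02. A local effect of the knockout allele was not tested.

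Probe sets with no single gene symbol held no difference past the threshold. Of 17824 tested with limma, 0 passed and 857 had an unadjusted p under 0.05, with a lowest adjusted p of 0.928.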
